A study of Mus musculus with 9 samples.

How the data were processed

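The data are CUT&Tag peak lists from mouse bone marrow. CUT&Tag cuts and tags DNA next to an antibody-bound protein with a tethered transposase, so that reads pile up where the protein or histone mark lies. The 9 libraries fall into 7 groups. DEK, a chromatin-bound protein, was profiled in 3 libraries of sorted haematopoietic stem cells (HSC, about 20000 cells) from control mice with a floxed Dek gene and no Cre (fl). The acetylation mark H3K9ac was profiled in HSC, and H3K27ac (an acetylation mark) and H3K4me3 (a promoter mark) in the broader stem and progenitor gate LSK (about 50000 cells). Each of these 3 marks has 1 fl library and 1 library from mice in which Tie2-Cre deletes Dek (cKO). All mice were 12 weeks old.

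Per the submitters' processing notes, Bowtie2, Picard and MACS2 were used with the mm10 genome. Their versions, the order of steps, any control track and the peak-calling threshold are not given in the sources used here. The row names within the DEK list of replicate 3 carry a Flag stem, whereas those of replicates 1 and 2 carry a DEK stem. Row names of replicate 3 and of both H3K9ac lists also carry a stem for removed duplicates, which the other lists lack, and the treatment of duplicates in those is not given. The antibody of replicate 3, and whether it shares a batch with H3K9ac, is therefore not certain, and the labels, which call it DEK, were followed. The authors deposited 1 peak list per library, so peaks were called per sample and not on pooled replicates. In each list the deposited score is 10 times the −log10 p truncated to a whole number. The deposited fold enrichment is a ratio of the peak summit over the caller's background within that library. The −log10 p and −log10 q (p-value and q-value) of each peak are the authors' own values. The lowest −log10 p of the regular rows lies between 5.00 and 5.09 in every list. Scores, folds and q-values were used only to rank or filter peaks within a list, and no peak height was compared between libraries. The lists carry no read counts, so the read depth of each library is unknown. A longer list may therefore come from deeper sequencing or lower background as well as from more marked places.

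Peaks on chromosomes 1 to 19, X and Y were used, and 16 mitochondrial peaks of the DEK lists were left out. Each row was checked for a strand mark, for a score within 1 of its rule, for −log10 q rising with −log10 p (against the 6 neighbours on either side), and for coordinate order. In the DEK lists 11 rows broke at least 1 of these rules and were left out. The 6 histone lists held 0 such rows. These checks, and leaving the rows out, were chosen after the rows had been seen, and the result with the 11 rows kept is given as an alternative. Coordinates are mm10, counted from 1.

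Peaks of different lists that overlapped by at least 1 bp were joined into regions, and a region was called shared, fl only or cKO only. Gene positions came from NCBI RefSeq for the GRCm38.p6 assembly (the mm10 coordinates), with 21887 protein-coding genes. The gene table used gives no strand. The planned window of 1 kb around the transcription start was therefore replaced, after the table had been seen, by windows of 1 kb around both annotated ends of a gene. Such a window can hold a 3′ end, and it misses a promoter that lies inside the annotated span. Random placements of peaks within their chromosome (100 of them) were made with bedtools 2.31.1. Shares carry a 95% exact binomial (Clopper-Pearson) interval, which covers counting error only. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

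The comparisons, the alternatives, the gene lists and the rule for named genes were otherwise fixed before the data were examined. With 1 library per genotype and mark, no test between genotypes was possible and none was run. A list's number of cKO-only genes minus fl-only genes was placed as a percentile among 10000 random gene lists of equal size. These were matched on the fl H3K4me3 class of each gene (no peak, or 1 of 5 rank classes), or on the fl H3K27ac class where H3K4me3 itself was compared. For DEK, the number of list genes with a peak gave an empirical two-sided permutation p over 10000 matched random lists, adjusted over lists by Benjamini-Hochberg. The share of cKO-only regions with a DEK peak was set against 10000 draws of shared regions matched on the decile of within-list rank.

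The 17 gene lists were study genes (6 genes named in work on DEK in these cells, so not independent of the study), HSC identity, quiescence, cell cycle, AKT and mTOR, oxidative phosphorylation, ribosomal proteins, acetylation machinery, chromatin, interferon and inflammation, p53 and apoptosis, myeloid, lymphoid, erythroid and megakaryocyte, endothelial, stromal, and non-blood genes. Of their 439 distinct genes, 438 were found in the gene table. Named genes were the 6 study genes, up to 12 genes with a DEK peak in all 3 libraries, for each mark the 10 cKO-only and 6 fl-only genes with the highest −log10 q, and up to 4 members of each list. Genes named outside this rule are marked as chosen after their values were seen.

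Alternatives were a −log10 q of at least 5, an overlap of at least 50% of the shorter peak, both lists limited to the length of the shorter one, windows of 3 kb, leaving out each DEK replicate, and DEK regions of all 3 or of any library. Added after seeing the data were the irregular rows kept, only gene ends with an H3K4me3 peak, whole gene bodies, merged regions in place of peaks, and region counts without places that also carried DEK or H3K9ac peaks or only with H3K4me3. The steps were tested on simulated data. In 2 simulated lists of 2000 peaks, 400 of 400 planted overlaps were found. Of 200 random lists drawn from 21887 genes, 7 fell outside the central 95% of matched lists. Of 200 lists with a planted rise of 40 percentage points, 199 lay above it, and smaller rises were not simulated. The row checks found 10 of 10 planted irregular rows and 0 of 1990 others.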

Results

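Chromatin was profiled in stem and progenitor cells of mice with and without DEK to ask where DEK sits and which active histone marks differ once it is lost. The DEK lists of fl HSC held 2054, 2111 and 6147 usable peaks in replicates 1 to 3 (mean 3437 ± 2347, SD, n = 3). For H3K27ac in LSK cells there were 10494 peaks in fl and 16331 in cKO. H3K9ac in HSC gave 2172 and 3431 peaks, and H3K4me3 in LSK cells 10514 and 10159. H3K4me3 was the mark most tied to genes: 79.9% of its fl peaks lay within 1 kb of a gene end, against 4.04% of randomly placed peaks. The share was 38.8% in the fl and 51.5% in the cKO H3K27ac list. It was 5.85% and 6.15% in the H3K9ac lists, against random means of 3.36% and 3.35%. Each mark had 1 library per genotype, so no difference between fl and cKO below has a replicate check.

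The first comparison asked where DEK peaks lay and whether the replicates shared them. DEK peaks were not concentrated at gene ends: 2.82% ± 0.408 (SD, n = 3) lay at a gene end, against 3.45% for random placements, and 39.5% ± 0.235 lay inside gene bodies only. Joined into 9685 regions, 488 regions had a peak in at least 2 libraries and 129 in all 3, where random placement gave a mean of 8.42 and 0. Replicate 1 shared 8.33% of its peaks with replicate 2 and 14.1% with replicate 3, so most peaks were seen in 1 library. Without replicate 1, 2 or 3 in turn, the regions in both remaining libraries numbered 291, 285 and 169. The regions ranked highest in all 3 libraries were outside annotated genes, at chromosome 2 (98666253 to 98667329), chromosome 14 (124801559 to 124802243) and chromosome 9 (3023420 to 3024693). The chromosome 2 region had a −log10 q of 3320, 3899 and 7663 in the 3 libraries. It also held an H3K9ac peak in fl and an H3K27ac peak in fl and in cKO, the strongest shared H3K27ac region away from gene ends (−log10 q 244). All 3 regions held a fl H3K9ac and a fl H3K27ac peak and no fl H3K4me3 peak. Peaks were not filtered for repeated sequence, so DEK binding at these places was not told apart from signal that arises whatever the antibody.

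Protein-coding genes with a DEK peak at an end numbered 63, 67 and 151 in the 3 libraries, 264 in any library, 14 in at least 2 and 3 in all 3. The 3 genes were Gm32584, Mfap2 and Asmt. Mfap2, a microfibril component, had its DEK peak at chromosome 4 from 141009166, with a fold enrichment of 12.1, 13.4 and 17.0 in the 3 lists. Asmt, the last enzyme of melatonin synthesis, had folds of 8.37, 13.2 and 24.0. Among genes with a peak in 2 libraries, chosen after their values were seen, Wls, a carrier of Wnt proteins, had the highest folds (27.9 and 42.9). Gp9, a platelet glycoprotein gene, had folds of 17.9 and 6.31 in replicates 2 and 3.

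The fixed gene lists held few DEK peaks. Gp9 in the erythroid and megakaryocyte list was the 1 list gene with a peak in at least 2 libraries (permutation p = 0.0336, adjusted p = 0.571 over the 17 lists), and without replicate 2 or replicate 3 the count was 0. In any library, that list had 2 genes (Car1 and Gp9). There was 1 each in the lists of study genes and cell cycle (Ccnb2), HSC identity (Mecom), AKT and mTOR and ribosomal proteins (Rps6), and non-blood genes (Actn2). The lists of quiescence, oxidative phosphorylation, acetylation machinery, chromatin, interferon and inflammation, p53 and apoptosis, myeloid, lymphoid, endothelial and stromal genes had 0. Every adjusted permutation p for a peak in any library was 1.0. With the 11 irregular rows kept, an alternative chosen after seeing the data, the count of list genes in at least 2 libraries was 3 in place of 1.

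The study genes were then read one at a time. In the regular DEK rows, Akt1, Akt2, Dek and Ncor1 (Akt1 and Akt2 encode AKT kinases, Ncor1 a corepressor) had no DEK peak within 1 kb of the gene. Ccnb2, the cyclin B2 gene, had 1 in replicate 3 at chromosome 9 (70420956 to 70422188), with a fold of 3.58 and a −log10 q of 2.04. Cdkn1a, which encodes the cell cycle inhibitor p21, had 1 in replicate 3 inside the gene at chromosome 17 (29093601 to 29094793), with a fold of 5.04 and a −log10 q of 3.37. These peaks were 1233 and 1193 bp wide, where the other rows with an equal −log10 p had a median width of 212 bp (1126 rows, widest 1192 bp) and 200 bp (4 rows, widest 270 bp). Both rows kept the format rules, and whether they belong with the irregular rows was left open. The irregular rows lay at 7 places. Akt1 carried 3 (all at chromosome 12, 112674445 to 112675692), Akt2 carried 3, Tgfb1 and Gata2 carried 1 each, and 1 lay at Map3k10.

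**Figure D1:**
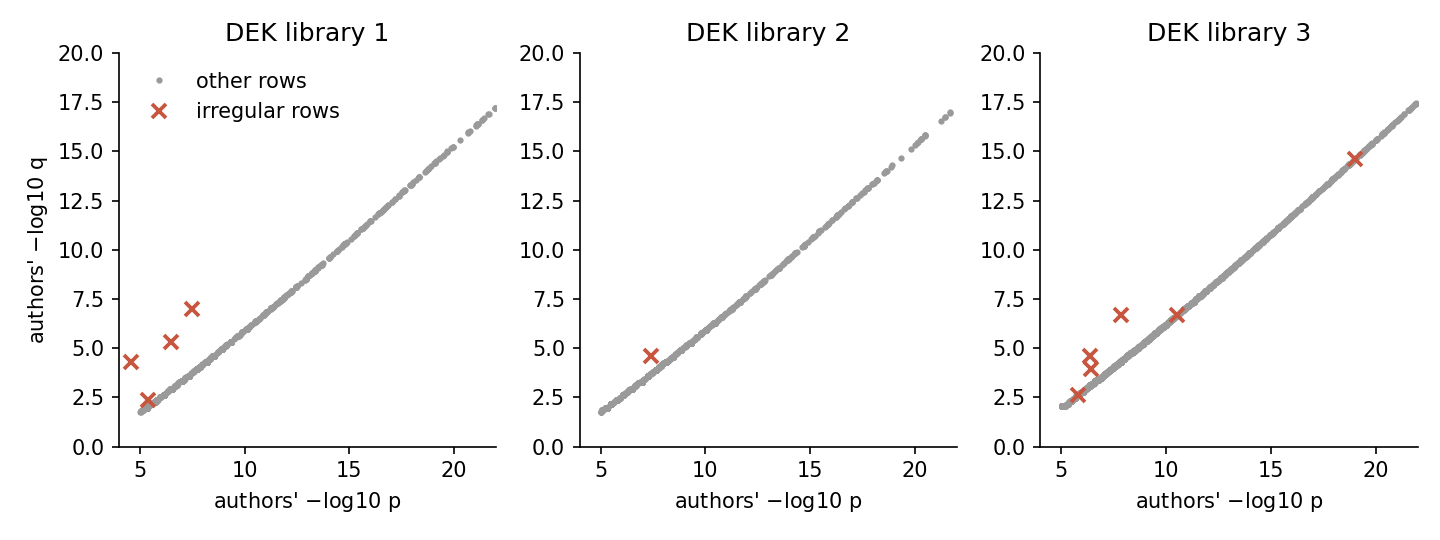
Each point is a row of a DEK peak list, with the authors' −log10 p on the x axis and −log10 q on the y axis, for the 3 DEK libraries (rows up to the axis limit). Crosses mark the 11 irregular rows, and 7 of these broke the relation of q to p that the other rows follow.

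DEK regions overlapped the acetylation marks but seldom H3K4me3. Of the 488 regions of at least 2 libraries, 116 (23.8%, 95% interval 20.1 to 27.8) overlapped a fl H3K27ac peak, against 0.469% of randomly placed regions. For fl H3K9ac the share was 32.2% (28.0 to 36.5), against 0.0717% at random. For fl H3K4me3 it was 3 regions (0.615%, 0.127 to 1.79), against 0.605% at random. Per library, 6.51% ± 2.27 of DEK peaks overlapped fl H3K27ac, 6.70% ± 0.546 fl H3K9ac and 0.568% ± 0.144 fl H3K4me3 (SD, n = 3). The H3K27ac share was 39.5% for regions of all 3 libraries and 6.29% for regions of any library. With the cKO lists the shares for regions of at least 2 libraries were 23.6% for H3K27ac and 39.8% for H3K9ac. The overlap was thus not particular to fl cells, and part of it may be independent of the antibody (see the flagged results below).

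The next comparison asked whether H3K27ac differed between fl and cKO LSK cells. The cKO list held an H3K27ac peak at an end of 9292 genes and the fl list at 4795. Of these, 4711 genes were in both, 4581 in cKO only and 84 in fl only. The cKO-only genes included Ncor1, Dek, Akt1 and Ccnb2. Of them 69.9% carried a fl H3K4me3 peak at an end, against 95.9% of the genes in both lists. By region, 9092 were shared, 7224 were cKO only (40.9%, 40.2 to 41.6) and 1346 were fl only (7.62%, 7.23 to 8.02). Gene ends made up 61.2% of the cKO-only regions (60.1 to 62.3) and 6.54% of the fl-only regions (5.28 to 7.99). With both lists at the length of the shorter one, 2983 regions were cKO only and 2934 fl only, a near-even split that equal lengths bring by construction. Gene ends were not bound in this way, and 2400 genes were cKO only and 422 fl only.

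**Figure D2:**
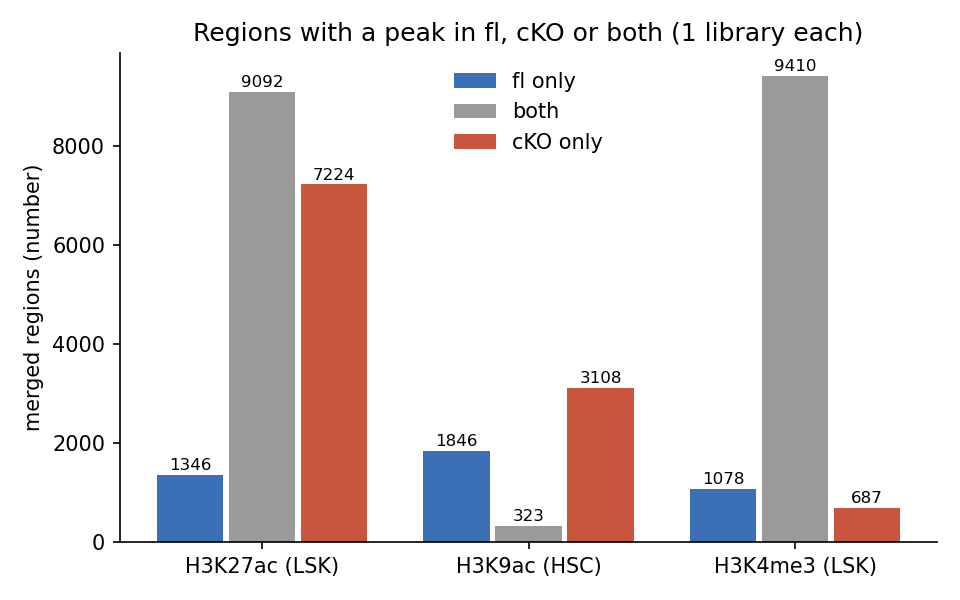
Bars give the number of merged regions (y axis) with a peak in fl only, in both or in cKO only, for each mark on the x axis, with 1 library per genotype. H3K27ac has 7224 cKO-only against 1346 fl-only regions, and H3K4me3 is mostly shared with 9410 regions.

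At the study genes H3K27ac differed in presence while H3K4me3 did not. Akt1 had an H3K27ac peak in cKO only, at chromosome 12 (112673577 to 112673962, fold 8.77, −log10 q 14.3). Ccnb2 had one in cKO only (fold 10.0, −log10 q 13.8), as had Ncor1 (fold 13.6, −log10 q 30.2) and Dek (fold 10.6, −log10 q 20.4). Akt2 had a peak in both lists. Cdkn1a had none at its ends, but 2 peaks inside the gene in cKO only (folds of 6.03 and 7.10), beside its H3K4me3 peak of both lists. This list's net gain stood at percentile 97.6 of matched lists, and the study chose these genes, so they are not independent evidence. Peaks at an end of Dek do not show whether the gene was deleted.

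All 17 lists had more cKO-only than fl-only H3K27ac genes. With lists of equal length 15 did, and 2 had equal numbers, non-blood genes (0 and 0) and erythroid and megakaryocyte genes (1 and 1). The cKO-only genes then numbered 6 for HSC identity, 6 for quiescence (1 fl only), 6 for acetylation machinery, 4 for oxidative phosphorylation and 7 for cell cycle (2 fl only). They numbered 3 for interferon and inflammation, 2 for endothelial, 1 for myeloid and 1 for stromal genes. HSC identity had 13 of 29 genes in cKO only, 2 in both and 0 in fl only (percentile 95.5), with the transcription factor genes Hlf (fold 13.1) and Mecom (9.82), and Kit, the stem cell factor receptor (9.73). The fl peak of the Mecom region lay just outside the window. Quiescence had 10 of 27 in cKO only (percentile 91.7), with the transcription factor genes Egr1 (9.86) and Foxo1 (6.79). AKT and mTOR had 14 of 32 (percentile 97.1), with Tsc1 (12.7), Rheb (10.9) and Pdpk1 (13.7), the kinase that activates AKT. Acetylation machinery had 10 of 23 (percentile 95.6), with Ncor1 and the deacetylases Hdac5 and Sirt1 (10.5). These values are the authors' folds within the cKO list.

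Lists of general upkeep gained peaks too, near the number that matched lists gave. Cell cycle had 11 of 40 genes in cKO only (Cenpa, Ccnb1, E2f2 and Ccne1 lead) and 1, Mcm7, in fl only (percentile 22.4). Oxidative phosphorylation had 9 of 40 (percentile 16.7), with Ndufv2 (14.7) and Uqcrfs1 (11.8) of the respiratory chain. Ribosomal proteins had 12 of 40 (percentile 62.4), with Rpl32 (13.2) and Rps7 (12.7). Chromatin had 7 of 27 (percentile 47.3), with the methyltransferase gene Kmt2a (12.7) and the Polycomb gene Eed (13.8). Interferon and inflammation had 5 of 28 (percentile 23.2), with Relb (14.5) and Socs1 (10.4), and p53 and apoptosis 6 of 22 (percentile 56.2), with Apaf1 (11.6) and Bcl2 (13.0).

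Lineage lists and lists of other tissues held H3K27ac in 0% to 19.2% of their genes in fl, against 21.9% of all genes. HSC identity was in this range too (6.90%), so a low fl share was not particular to them. Myeloid genes had 3 of 24 in cKO only (percentile 11.4), which were Cebpa, Cebpb and Cebpe. Lymphoid genes had 8 of 26 in cKO only, among them Ikzf1 (10.4) and Satb1 (11.9), and 1, Lck, in fl only (percentile 86.0). Erythroid and megakaryocyte genes had 2 of 26, Zfpm1 and Gp1bb (percentile 8.38). Endothelial genes had 6 of 18 in cKO only and 0 in fl (percentile 87.1), led by the growth factor receptor gene Kdr (10.0). Stromal genes had 3 of 18 and 0 in fl (percentile 71.0), which were Alpl, Sp7 and Cxcl12. Non-blood genes had 6 of 24 in cKO only and 0 in fl (percentile 97.2), among them the neuronal gene Neurod2 (7.33) and the gut genes Lgr5 (7.80) and Cdx2 (7.89), and all of these were gone with lists of equal length (0 in cKO only). Over the 3 marks, 2 of 51 list percentiles (1 on each side) lay outside the central 95%, where 2.55 are expected by chance.

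**Figure D3:**
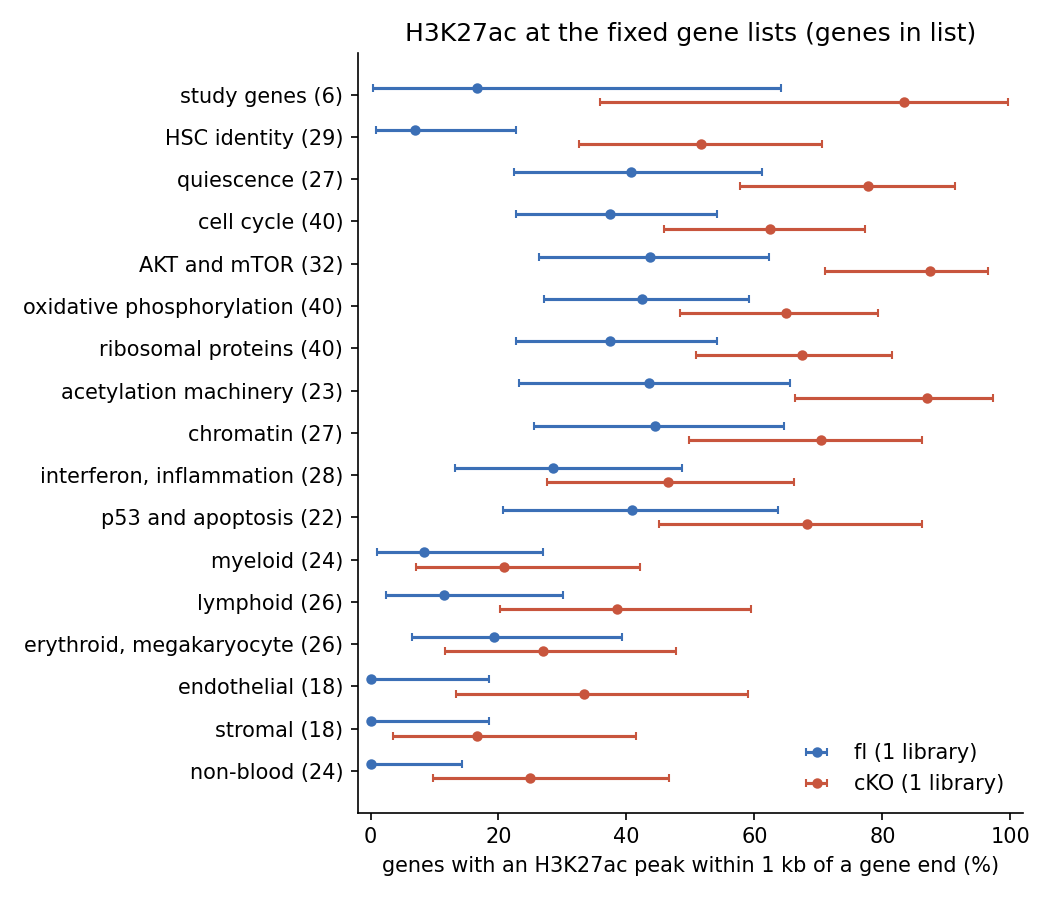
Points give the percent of each fixed list (genes in brackets) with an H3K27ac peak within 1 kb of a gene end in fl and in cKO, and bars the 95% exact binomial interval, which covers counting error only. The cKO value is above the fl value in all 17 lists, including ribosomal proteins (15 genes in fl and 27 in cKO) and non-blood genes (0 and 6).

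The cKO-only genes with the strongest peaks were, by −log10 q, Gm40369 (59.0), Mtln (57.8), Fnta (56.7), Sec22c (53.1), Entpd4b (52.1), LOC115488278 (52.1), Entpd4 (51.9), Egln2 (48.1), Elovl1 (47.4) and Pigv (47.2). Fnta, a farnesyltransferase subunit gene, had its peak at chromosome 8 (26015132 to 26015768), and Egln2, a prolyl hydroxylase of the hypoxia response, at chromosome 7 (27166341 to 27166990). For Gm40369, Mtln, Elovl1 and Pigv the peak belonged to a region shared with fl whose fl peak lay outside the window, so these 4 are differences in peak edges. The strongest fl-only genes were Gm21805 (33.7), Strada (19.8), Ddit3 and Mbd6, which share a peak (14.9), Gm2046 (14.0) and Efcab7 (13.0). The Gm21805 peak, too, belonged to a shared region. Over all 4581 cKO-only genes, 53 had their peak in a shared region.

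The share of cKO-only regions rose from the strong to the weak end of the cKO H3K27ac list. In the strongest decile 2.08% of regions were cKO only (1.45 to 2.90), and in the weakest 81.7% (79.7 to 83.5). The fl list went from 0% (upper limit 0.351) to 15.6% (13.4 to 17.9), with a maximum of 22.9% in decile 8. For H3K4me3 the cKO-only share was 0% in each of the strongest 5 deciles and 43.8% in the weakest.

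**Figure D4:**
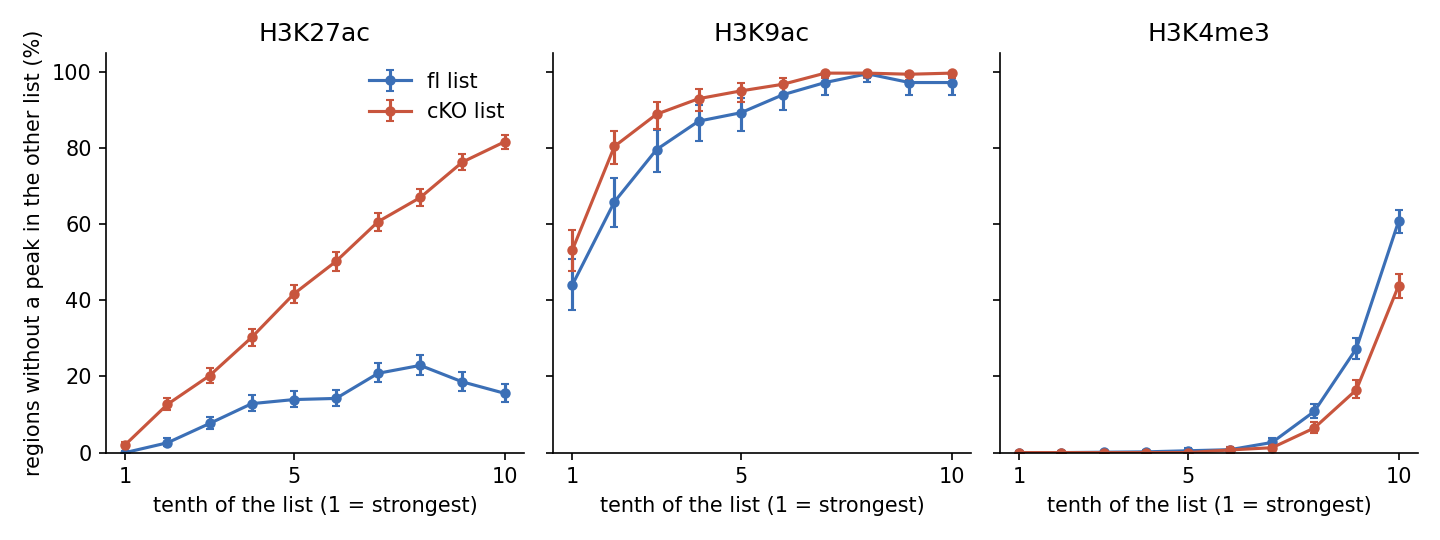
For each mark, the percent of regions of a list without a peak in the other genotype's list (y axis) is plotted by decile of within-list rank (x axis, 1 is strongest) for the fl and cKO lists, with 95% exact binomial intervals. H3K27ac of the cKO list climbs from 2.08% to 81.7%, H3K4me3 is near 0 until the weak deciles, and H3K9ac reaches 97.2% (fl) and 99.7% (cKO) in the weakest decile.

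Whether the cKO-only acetylated regions were places with a DEK peak was asked next. Among cKO-only H3K27ac regions 14 of 7224 overlapped a DEK region of at least 2 libraries (0.194%, 0.106 to 0.325), against 108 of 9092 shared regions (1.19%, 0.975 to 1.43) and 15 of 1346 fl-only regions (1.11%, 0.625 to 1.83). Shared regions matched on rank gave a mean of 1.40% (central 95% of draws 1.13 to 1.68), and the cKO-only value lay below all 10000 draws. By single DEK library the shares were 0.420% ± 0.165 for cKO-only and 2.53% ± 2.49 for shared regions (SD, n = 3). With DEK peaks of any library the cKO-only share was 0.955% (0.744 to 1.21), against 0.282% for random placement of the same regions (0.152 to 0.429 over 100 placements). Among regions with an H3K4me3 peak the shares were 0.235% for cKO-only (0.108 to 0.446) and 0.334% for shared regions (0.187 to 0.551), and the cKO-only value stood at percentile 47.9 of rank-matched draws. Among regions without an H3K9ac peak the shares were 0.672% (0.496 to 0.891) and 4.47% (4.05 to 4.92), at percentile 0.0. These restricted comparisons were chosen after the data were seen.

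For H3K9ac in HSC the lists of fl and cKO had little in common. Their peaks were weak, with a median −log10 q of 2.42 in fl and 2.48 in cKO. Few lay at gene ends (5.85% and 6.15%, against 3.36% and 3.35% at random). Acetylation and background cannot be told apart in these lists, so the differences and genes named from them need not reflect the mark. Only 323 regions were shared, beside 3108 cKO-only (58.9%, 57.6 to 60.2) and 1846 fl-only regions (35.0%, 33.7 to 36.3). At gene ends 232 genes had a peak in cKO and 144 in fl, of which 11 were in both. Of the shared regions 79.0% (74.1 to 83.3) overlapped a DEK peak of any library (36.8%, 32.8% and 76.2% for replicates 1, 2 and 3 alone) and 1.24% (0.338 to 3.14) an H3K4me3 peak. The cKO-only regions were 740 and the fl-only regions 329 at a −log10 q of at least 5, and 1854 and 1851 with lists of equal length, where the order of genes turned (132 cKO only and 134 fl only).

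The strongest cKO-only H3K9ac genes were Gnl1 (−log10 q 64.1), the interferon-induced gene Ifi44l (51.6), Eif4ebp2, a repressor of translation (47.0), Pou2f1 (fold 15.0), Dnajc3 and Uggt2 (17.2, the pair sharing a peak), Paip1 (11.8), Adgb (11.7), C1qtnf1 and Arrb1 (10.4). Ifi44l also had a DEK peak at the same end in DEK replicates 2 and 3. The fl-only genes were Zcchc24 (23.9), Slc44a3 (12.0), Gm36028 (11.2), Npffr2 (9.49), Rapsn (8.88) and Elmod3 (8.59). None of the 6 study genes had an H3K9ac peak. Among the lists, oxidative phosphorylation had 2 genes in cKO only, Uqcrfs1 and Ndufv1 (percentile 95.9). AKT and mTOR (Pdpk1), myeloid (Itgam), lymphoid (Ccr9), erythroid and megakaryocyte (Gp9) and endothelial genes (Kdr) had 1 each in cKO only. HSC identity (Lyl1), quiescence (Cdkn2c) and interferon and inflammation (Jak1) had 1 each in fl only, and the lists of cell cycle, ribosomal proteins, acetylation machinery, chromatin, p53 and apoptosis, stromal and non-blood genes had 0. At a −log10 q of at least 5 only Gp9 of these list genes was left, so the other list calls rest on weak peaks. The Gp9 peak (chromosome 6, 87775318 to 87775668) had the same start and end as the Gp9 peak of DEK replicate 3.

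H3K4me3 was largely shared between fl and cKO LSK cells. Of its regions 9410 were shared (84.2%, 83.5 to 84.9), 687 were cKO only (6.15%, 5.71 to 6.61) and 1078 fl only (9.65%, 9.10 to 10.2). At gene ends 8993 genes had the mark in both lists, 348 in cKO only and 601 in fl only. Akt1, Akt2, Ccnb2, Dek and Ncor1 had it in both, with folds of 10.7 in fl and 10.8 in cKO at Ncor1. Myeloid genes had 4 fl-only members, Mpo, Ly6c2, Irf8 and Spi1, and 1 cKO-only member, S100a8 (percentile 1.22). Here Mpo encodes a neutrophil granule enzyme (−log10 q 9.92 in fl) and Irf8 and Spi1 encode myeloid transcription factors. The peaks of Mpo, Ly6c2 and Irf8 ranked 8717, 9368 and 9691 among the 10514 of the fl list. In deciles 9 and 10 of that list 27.4% and 60.7% of regions were fl only, so such calls were common at this strength.

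The other H3K4me3 lists had a net difference of 2 genes or fewer. Fl-only members were Igll1 and Dntt of the lymphoid list (percentile 7.45), Ramp2 and Tie1 of the endothelial list (percentile 4.29), and Pdgfrb of the stromal list (percentile 19.7). HSC identity had 2 genes in cKO only, Hlf and Lmo2, and 2 in fl only, among them Procr (percentile 59.8). Cell cycle had Ccnd1 in cKO only and Mcm2 and Bub1b in fl only (percentile 33.9). Erythroid and megakaryocyte genes had Hbb-bt and Rhd in cKO only and 1 gene in fl only (percentile 88.5), and interferon and inflammation had Ifit2 in cKO only (percentile 88.8). Gfi1 (quiescence, percentile 24.0), Eif4e (AKT and mTOR, percentile 28.2), Atp5d (oxidative phosphorylation, percentile 33.6) and Rpl19 (ribosomal proteins, percentile 32.5) were each the 1 fl-only gene of their list. The Eif4e peak belonged to a region shared with cKO whose cKO peak lay outside the window, so it is a difference in peak edges. Study genes, acetylation machinery, chromatin, p53 and apoptosis, and non-blood genes had 0 on either side. Hlf (−log10 q 4.92), Lmo2 (3.63), Procr (3.02), Hbb-bt (3.98) and Rhd (3.54) were below a −log10 q of 5, so these calls rest on weak peaks. The other genes named in this paragraph were above it.

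By −log10 q, the strongest H3K4me3 genes in cKO only were Wapl (55.2), Erbb3 (43.3), Stx4a (29.4), Lrrc24 (28.4), Pnisr (21.5), Dera (18.7), Septin4 (18.2), Amdhd1 and Ccdc38, which share a peak (17.5), and the agouti gene a (16.4). In fl only they were Ddx6 (112.0), Rhbdl1 (70.7), Kank3 (66.3), Spidr (62.6), Bbs7 (58.2) and Trafd1 (50.6). For 6 of the 10 cKO-only genes and 6 of the 6 fl-only genes the peak belonged to a shared region that crossed the edge of the window. Dera, Amdhd1, Ccdc38 and a were the 4 with a region of the cKO list alone.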

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

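The tests of list length and of DEK occupancy were set before their result was seen, and the other tests in this part, the restricted DEK comparisons among them, were chosen after it. A signal outside the main measurement led to a closer look at a pair of items. The 3 DEK lists held 11 irregular rows, which the comparisons leave out. They also held 16 mitochondrial peaks (5, 4 and 7 in replicates 1 to 3), while the 6 histone lists held 0.

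The irregular rows of the DEK lists are defined by the rules they broke: 7 lacked a strand mark, 9 had a score off its rule, 7 had a q off the relation to p, and 9 stood out of order. Picked by the strand mark alone, 7 of 7 rows also broke the score rule (100.0%, 59.0 to 100.0), against 2 of 10332 DEK rows with the mark, which argues against the same caller output for these 7. Of the other 4 irregular rows 50.0% broke the score rule (6.76 to 93.2), and since rows were picked by it their source stays open. Arbitrary placement is argued against, since 2 of the 7 distinct places (28.6%, 3.67 to 71.0) lay within 1 kb of an end of 1 of the 6 study genes, Akt1 and Akt2, against 1 of 10303 places of other DEK peaks. Where the rows came from was not tested, another or pooled peak call among the open sources, and no biological explanation was tested.

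Many more gene ends had an H3K27ac peak in cKO than in fl (9292 and 4795 genes). A difference in list length alone is argued against, since with lists of equal length cKO-only gene ends still outnumbered fl-only ones 5.69 to 1. Few cKO-only regions had a called DEK peak: DEK peaks of any library touched 0.955% of them, against 0.282% with random placement. At gene ends they touched 8 of the 4422 cKO-only regions (0.181%, 0.0781 to 0.356). Most cKO-only regions thus held no called DEK peak. The DEK lists had a peak at an end of 264 genes in any library, so few overlaps at gene ends were bound to be found. These shares therefore cannot decide whether loss of DEK was the source. The cKO-only regions stood at percentile 0.0 of rank-matched shared regions, also without places with an H3K9ac peak. That comparison cannot decide, since places with signal whatever the antibody would count as shared and as holding DEK. At gene ends the percentile was 0.350 for DEK regions of at least 2 libraries (0 of 4422 cKO-only and 2 of 3997 shared regions) and 6.91 for any library, among H3K4me3-marked regions it was 44.1 and 47.9, all on few overlaps, and DEK below the reach of the peak lists was not tested. A lower sensitivity of the fl list may account for the pattern, as the cKO-only share was 39.2 times higher in the weakest than in the strongest decile, and a broad gain of acetylation without DEK would give the same gradient, so it stays open with 1 library per genotype.

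The DEK regions shared between libraries may be partly independent of the antibody. Of the 129 regions of all 3 libraries, 79 (61.2%, 52.3 to 69.7) carried an H3K9ac peak in fl and in cKO, and 1 (0.775%, 0.0196 to 4.24) an H3K4me3 peak. H3K27ac peaks of both genotypes covered 34.9% (26.7 to 43.8). A real joint presence of DEK and acetylation at these places stays open, since no library with a control antibody and no cKO DEK library was analysed here.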

How the results depend on the processing

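The alternatives with irregular rows kept, H3K4me3-marked ends, gene bodies, merged regions and region filters were chosen after seeing the data. At a −log10 q of at least 5, DEK regions of at least 2 libraries fell from 488 to 284, cKO-only H3K9ac regions from 3108 to 740 and cKO-only H3K9ac genes from 221 to 26 (in the fixed lists from 7 to 1), with fewer peaks left by construction. With lists of equal length, cKO-only H3K27ac regions were 2983, genes 2400 and fixed-list genes 75 (from 124), and cKO-only H3K9ac regions were 1854. H3K9ac genes then turned to 132 cKO only against 134 fl only, with the fewer cKO peaks as built. H3K9ac genes in cKO only were 448 within 3 kb, 110 at H3K4me3-marked ends and 1273 over gene bodies, where the net order turned in HSC identity (3 cKO only, 2 fl only) and in interferon and inflammation (2 and 1). The share of DEK regions with fl H3K27ac was 39.5% for regions of all 3 libraries and 6.29% for any library, and cKO-only H3K27ac regions with a DEK peak of any library 0.955%. Without 1 DEK replicate, shared regions ranged from 169 to 291, the H3K27ac share from 26.0% to 32.5%, the cKO-only share with DEK from 0.138% to 0.166%, and list genes with DEK from 0 to 1; 169 was without replicate 3. With the irregular rows kept, list genes with DEK were 3. Among H3K4me3-marked regions, cKO-only H3K27ac regions were 3824. Beyond the construction of each alternative, the cause was not tested. Over all settings, the named genes kept their state in 433 of 498 values for H3K27ac, 159 of 192 for H3K9ac and 323 of 375 for H3K4me3. For H3K27ac, cKO-only genes outnumbered fl-only genes in the totals of all genes and of the fixed lists in every setting run. By list, 15 of 17 kept this order with equal lengths (non-blood, and erythroid and megakaryocyte genes, tied) and 15 with H3K4me3-marked ends. No paired analysis was possible because each mark has 1 library per genotype. Read depth is not in the lists and limits every absence of a peak.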

Other observations

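The widths of H3K4me3 peaks were described after the comparisons, and these tests and genes were chosen after the data were seen. Among 8993 genes with the mark at an end in both lists the median width was 868 bp in fl and 818 bp in cKO. The widest peaks lay at Cdk6, a kinase of early cell cycle entry (3591 bp in fl and in cKO), Msl2 (3142 and 3147 bp), Ppp1r9b (3063 and 2870 bp) and Zfp36l2, an RNA-binding regulator of blood progenitors (3205 and 2588 bp). Foxo3, a transcription factor of stem cell quiescence, had 2690 and 2473 bp, and Junb 2379 bp in both.

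Quiescence genes had the widest peaks of the fixed lists, with a median of 1638 bp in fl and 1291 bp in cKO over 20 genes (percentile 100.0 of 10000 random lists in both). Chromatin genes followed with 1301 and 1243 bp (23 genes), led by Cbx5, Ctcf and Kmt2a. HSC identity genes had 1160 and 1083 bp (21 genes, percentiles 99.7 and 99.6), led by Lyl1, Tal1 and Prdm16. Acetylation machinery (1145 and 1157 bp, percentiles 99.6 and 100.0), ribosomal proteins (1069.5 and 990.5 bp, 99.6 and 99.3) and cell cycle genes (1106.5 and 965.5 bp, 99.9 and 98.3) were as far out, so wide peaks were not particular to stem cell lists. Oxidative phosphorylation genes were near the median of all genes (895 and 831 bp), and endothelial genes were narrower (573 and 603 bp, 5 genes). The 6 myeloid genes had 1145.5 bp in fl and 738 bp in cKO (percentiles 93.2 and 30.0).

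Away from gene ends, the strongest cKO-only H3K27ac regions were on chromosome Y (90771853 to 90772878 and 90765337 to 90765913), with a −log10 q of 106.0 and 95.9. Next came chromosome 8 (123623585 to 123624187) and a region inside Zfp710, a zinc finger gene, on chromosome 7 (80026800 to 80027402, fold 13.7). The strongest fl-only region lay on chromosome 15 (52648853 to 52649345), with a −log10 q of 30.5. The sample details used here do not give the sex of the mice, and peaks were not filtered for repeated sequence. Without replicate libraries, a difference in sex or in read mapping was not told apart from one in acetylation. The chromosome Y regions in particular need not reflect the loss of DEK.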
